A study of Mus musculus with 12 samples.

How the data were processed

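Nuclei from the caudal forelimb area of the primary motor cortex of the right hemisphere of 6 mice, 13 weeks old, were measured by droplet-based single-nucleus RNA sequencing with 3' capture. Per the labels, 3 mice (1, 3 and 5) were controls kept on restricted water in the home cage, and 3 mice (2, 4 and 6) pressed a lever for part of their water on days 11 to 13. Each mouse was sequenced in 2 runs, a shallow one and a deep one, and the deposited matrix joins both runs and all 6 mice, so the runs could not be separated and each mouse is 1 replicate. The barcode suffix gave the mouse, as the design text of the series states. The labels speak of separate animals, so spread between replicates is spread between mice.

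The authors deposited 1 matrix of whole-number UMI counts per gene and nucleus, and every value in it was a whole number. Reads were processed with Cell Ranger 4.0.0 against the mouse build mm10, per the submitters' processing notes. Whether intronic reads were counted, whether depth was equalised between mice when they were combined, and which barcode filter was applied before deposit are not given in the sources used here. The lowest total per barcode ranged from 500 to 512 UMIs between mice. The deposited lists of barcodes and genes (neither counts nor scores) were used to assign nuclei to mice and to name genes. Gene positions came from the GENCODE M21 annotation of mm10.

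Of 51926 barcodes, 51683 had at least 500 detected genes and under 5% mitochondrial UMIs, and 243 were left out. Scrublet, run per mouse through scanpy 1.11.5 with an expected doublet share of 6%, marked 2391 doublets, between 3.29% and 5.70% per mouse, and 49292 nuclei were kept. Counts were scaled per nucleus and log-transformed, 2063 variable genes were used for 30 principal components, and nuclei were clustered with Leiden (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0 on a graph of 20 neighbours. Activity-regulated, stress, clock, glucocorticoid, heat shock, mitochondrial and sex-linked genes were left out of the variable genes, so that clusters did not follow them. No deposited cell annotation was used. Clusters of at least 20 nuclei took the name of the class with the most fixed marker genes among the 10 leading genes by fold over the other clusters (5 CPM added), with ties settled by the mean marker level. A name needed at least 1 such marker and at least 3 markers detected in 10% or more of the nuclei of the cluster. Clusters without a name kept their number from 500 nuclei and otherwise stayed unnamed. Each name stands for "-like", for example L2/3 IT-like for intratelencephalic neurons of layers 2 and 3, and ET, NP and CT stand for extratelencephalic, near-projecting and corticothalamic. Cluster 10, a glutamatergic cluster whose leading genes included Scn7a, Hgf and Cpne4, met no name and kept its number. Naming gave 22 classes. L6b and differentiating oligodendrocyte-like nuclei had under 20 nuclei in at least 1 mouse and were not fitted.

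UMI counts were summed per mouse within each of 20 classes and over all nuclei, which gave 21 sets of sums. Trained and control mice were compared by edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood test, TMM scaling and filterByExpr, and p-values were adjusted by Benjamini-Hochberg within each class with a threshold of 0.05. CPM values (counts scaled to a common library total) are TMM-scaled unless stated, errors of means are SD over 3 mice, and errors of log2 fold changes are standard errors. The interaction of training with class used both sums of each mouse with mouse as a block. Gene lists (17) were tested by camera on voom values (limma 3.58.1) with a preset correlation of 0.01 for lists with at least 3 tested members, adjusted over all 330 tests, and again with estimated correlation and by fry. Shares of nuclei were tested by edgeR on counts of nuclei and by exact two-sided permutation, which for 3 against 3 mice cannot give a p below 0.1. DESeq2 1.42.0 was the other tool. Remaining steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

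Nuclei high in immediate early genes were those with 3 or more UMIs of a list of 25 detected genes after every nucleus was thinned at random to 2000 UMIs. Shallower nuclei, 9021 in all, were left out of that measure. In L2/3 IT nuclei, sums of high nuclei and of nuclei with 0 such UMIs were compared within mice, and the genes of the list itself were left out of the result.

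The groups, tests, marker genes, gene lists, the alternatives of the plan and the rule for naming genes were chosen before the data were examined. The rule named every detected immediate early gene in L2/3 IT and in all nuclei, the 10 higher and 10 lower genes of smallest p past the threshold there whose trained mice all lay beyond all controls, the 3 higher and 3 lower by the same rule in each other class, the 3 of smallest p each way in each interaction, the 4 members of smallest p of each called list, and the 10 higher and 10 lower genes and the delayed list in the comparison of high and low nuclei. Where nothing passed, it named the 3 genes of smallest p. Predicted genes and unnamed clones were skipped but counted. The text gives a selection of the genes that the rule allows and says where a gene outside it was chosen after its values were seen.

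The fits were tested on simulated counts for the real genes with 200 genes changed by 1.5, 2 or 3 times. Each gene was drawn independently, without differences between mice that many genes share, so recovery in the real sums can differ. In simulated L2/3 IT sums (13645 genes) 34.3%, 71.9% and 88.4% of genes changed by these folds were recovered, and in simulated astrocyte sums (12120 genes) 17.6%, 71.9% and 89.7%. Simulated sums of all nuclei (19355 genes) gave 31.8%, 69.6% and 88.5%, the other glutamatergic classes 22.2%, 65.4% and 90.1%, the GABAergic classes 22.5%, 61.4% and 89.3%, and the other non-neuronal classes 8.46%, 42.6% and 75.2%. For the interactions the shares were 39.3%, 65.7% and 79.8%, and for high against low nuclei (7158 genes) 39.0%, 79.7% and 91.5%. Pooled over the classes of each part, between 2.92% and 8.46% of simulated calls were false, and in microglia and macrophages alone 13 of 124 were.

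Alternatives were DESeq2, RLE size factors, no filter, at least 1000 genes per nucleus, doublets kept, sums thinned to the smallest total, the median UMIs per nucleus as a covariate, clustering at resolution 0.5, other thinning depths and UMI minimums, and leaving out each mouse in turn. Chosen after seeing the data were a robust fit, the mitochondrial percent as a covariate, the 3 mice of highest median UMIs as a block, and leaving out both mice 2 and 6, which leaves trained mouse 4 as the only trained mouse, assumed to vary like the control mice.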

Results

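The transcriptomes of 49292 nuclei from the caudal forelimb area of the mouse primary motor cortex were compared between 3 mice that practised a lever press for water reward (mice 2, 4 and 6) and 3 mice on the same water restriction without training (mice 1, 3 and 5). The series title places learning-related states of glutamatergic neurons at the centre. The matrix held 91495029, 84517778 and 56099142 UMIs for control mice 1, 3 and 5, and 62741326, 60629255 and 46798359 UMIs for trained mice 2, 4 and 6. Kept nuclei numbered 9651, 11817 and 7353 in the controls and 6839, 8367 and 5265 in the trained mice. Median UMIs per nucleus were highest in control mouse 1 (6874) and trained mice 2 (6843) and 6 (7205), and lower in control mice 3 (5215) and 5 (5302) and trained mouse 4 (5749). The mean mitochondrial share of UMIs was 0.0482% ± 0.00838 in control and 0.0758% ± 0.0297 in trained mice (SD, n = 3 each), with an exact two-sided permutation p of 0.2 where the smallest possible is 0.1. Trained mouse 2 had the highest share, 0.109%. Nuclei fell into 22 classes named from markers, each name meaning "-like", and 20 classes held enough nuclei in every mouse to be fitted.

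In L2/3 IT nuclei (5337 nuclei, 5696070 to 14662855 UMIs per mouse), no gene passed the threshold between trained and control mice by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The genes of smallest p were B4galt1, a galactosyltransferase of glycoprotein synthesis, at 15.9 ± 1.60 CPM in control and 27.0 ± 0.943 CPM in trained mice (SD, n = 3 each), Colgalt2, a collagen galactosyltransferase, at 12.7 ± 0.548 and 23.01 ± 3.14 CPM, and Etv1, an ETS transcription factor, at 32.7 ± 0.977 and 19.3 ± 2.56 CPM. Their log2 fold changes were 0.76 ± 0.12, 0.85 ± 0.14 and -0.75 ± 0.13 (SE), each with an adjusted p of 0.507 by edgeR. Of 13860 genes tested, 539 (3.89%) had an unadjusted p under 0.05, and DESeq2 called 6 (5 higher, 1 lower). In simulated sums of this class, 71.9% of genes with a doubling were recovered. Genes were simulated independently of each other, so the share for the real sums is not known.

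The immediate early genes, which neurons transcribe within minutes of activity, did not pass in L2/3 IT nuclei either over all genes or adjusted over the list alone (0 of 22 tested in both). Fos was at 23.5 ± 14.7 CPM in control and 18.7 ± 8.09 CPM in trained mice (SD, n = 3 each), Arc, a regulator of synaptic AMPA receptors, at 55.3 ± 20.03 and 59.2 ± 29.2 CPM, Egr1 at 57.1 ± 12.7 and 49.9 ± 18.5 CPM, and Npas4 at 19.7 ± 9.64 and 17.2 ± 9.43 CPM. Junb stood at 98.6 ± 53.1 and 91.2 ± 50.7 CPM and Nr4a1 at 76.1 ± 6.38 and 77.5 ± 26.6 CPM. Spread within each group exceeded the difference between groups for all 6 genes. Fosb, Fosl2, Egr2, Egr3, Egr4, Jun, Nr4a2, Nr4a3, Ier2, Ier5, Dusp1, Dusp6, Btg2, Gadd45b, Cyr61 and Fbxo33 did not pass. The list as a group was not called (adjusted p = 0.366 by camera, 15 of 22 members higher), and with an estimated correlation its adjusted p = 0.995.

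Among the other glutamatergic classes (L4/5 IT, L5 IT, L6 IT, L5 ET, L5/6 NP, L6 CT and cluster 10), none of 87184 gene tests passed. L5 IT nuclei came closest: Blnk, which encodes an adaptor of B cell receptor signalling, was at 45.8 ± 3.67 CPM in control and 82.5 ± 10.7 CPM in trained mice (SD, n = 3 each), and Prrg1, a membrane protein gene, at 85.4 ± 7.04 and 50.4 ± 5.10 CPM, with log2 fold changes of 0.84 ± 0.12 and -0.76 ± 0.11. The non-coding host gene Mir670hg (chromosome 2, 94160636 to 94264918, mm10) had a log2 fold change of 0.86 ± 0.12 in L5 IT and 1.30 ± 0.20 in cluster 10, where it went from 62.0 ± 2.40 to 153 ± 46.9 CPM. Nptx2, a secreted pentraxin that clusters AMPA receptors, was at 10.1 ± 2.12 and 25.2 ± 5.70 CPM in cluster 10, a log2 difference of 1.31 ± 0.22. In L5 ET nuclei, Lrfn2, a synaptic adhesion protein gene, was at 128 ± 14.8 and 194 ± 5.82 CPM. Adjusted p-values by edgeR were 0.112 for the 3 L5 IT genes, 0.242 and 0.265 for Mir670hg and Nptx2 in cluster 10, and 0.657 for Lrfn2.

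In these 7 classes 3113 tests (3.57%) had an unadjusted p under 0.05, and DESeq2 called 41 genes, 28 in L5 IT, 12 in cluster 10 and 1 in L5 ET. The count of 0 rose to 76, all in L5 IT, with the median UMIs per nucleus as a covariate, to 65 with the 3 deeper mice as a block, and to 2 without control mouse 1. It was 1 without control mouse 3, trained mouse 4 or trained mouse 6.

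In the GABAergic classes (Lamp5, Pvalb, Sncg, Sst and Vip), 1 of 48031 gene tests passed. The long non-coding RNA Gm28928 (chromosome 1, 124505757 to 124846039, mm10) rose in Sncg nuclei from 58.4 ± 40.2 to 340 ± 78.2 CPM (SD, n = 3 each), a log2 fold change of 2.77 ± 0.30 with an edgeR adjusted p of 4.03e-05. It is named although predicted genes are outside the naming rule, a choice made after its values were seen, and its count is uncertain because Gm28299 and Gm37717 overlap it on the same strand. Without passing, Mir670hg was at 105 ± 26.3 and 260 ± 87.7 CPM in Vip nuclei (adjusted p 0.0836), and Homer2, a postsynaptic scaffold gene, at 274 ± 15.0 and 410 ± 44.4 CPM in Lamp5 nuclei (adjusted p 0.428). Sox6, a transcription factor of interneurons from the medial ganglionic eminence, was at 32.4 ± 4.57 and 11.7 ± 6.08 CPM in Vip nuclei, where Sst, a marker of another interneuron class, was at 51.1 ± 20.4 and 20.3 ± 1.87 CPM (adjusted p 0.724 for both).

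Unadjusted p-values were under 0.05 in 1531 (3.19%) of the GABAergic tests, and DESeq2 called 2 genes. Gm28928 no longer passed with doublets kept. At clustering resolution 0.5 no cluster took the Sncg name, so Sncg nuclei were not fitted as a class of their own. The Vip cluster held 1210 nuclei there, against 947 Vip and 262 Sncg nuclei at resolution 1.0. None of 10053 genes passed in that larger Vip class. Counts were 3 without control mouse 1, 2 without trained mouse 2, 3 without control mouse 3 and 13 without trained mouse 4, and Sncg nuclei were few, 27 to 72 per mouse.

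Astrocyte nuclei (6067 nuclei, 2015492 to 4021935 UMIs per mouse) of trained mice showed 20 genes higher and none lower. Irs2 (chromosome 8, 10984681 to 11008458), an adaptor of insulin and IGF receptors, rose from 30.2 ± 4.10 to 102.5 ± 29.8 CPM (SD, n = 3 each), a log2 fold change of 1.76 ± 0.20. Map3k19 (chromosome 1, 127815253 to 127855031), a MAP kinase kinase kinase, rose from 58.6 ± 11.0 to 207 ± 70.3 CPM (1.82 ± 0.22), and Coq10b (chromosome 1, 55052770 to 55072702), a coenzyme Q-binding mitochondrial protein gene, from 66.9 ± 6.91 to 145 ± 9.41 CPM (1.11 ± 0.13). These 3 genes shared an edgeR adjusted p of 0.00246. The 20 genes rose between 1.77 and 9.52 times with adjusted p-values up to 0.0312, and for each of them all 3 trained mice lay above all 3 controls. Separation in either direction held for 13.1% of all astrocyte genes tested, where chance gives 10%.

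Of the immediate early list, 5 of 20 tested genes rose in astrocytes over all genes, Nr4a2, Nr4a3, Klf4, Cyr61 and Btg2, and 9 passed when adjusted over the list alone, 8 higher and 1 lower. The list alone added Fos, Junb and Nr4a1, which were higher, and Dusp6, a MAP kinase phosphatase gene, which was lower (log2 fold change -0.52 ± 0.18), with Nr4a1 and Dusp6 named after their values were seen. The orphan nuclear receptor gene Nr4a2 went from 2.84 ± 0.469 to 26.6 ± 19.6 CPM (SD, n = 3 each), Nr4a3 from 3.18 ± 0.901 to 21.9 ± 13.2 CPM, Klf4, a zinc finger transcription factor, from 2.11 ± 0.732 to 9.34 ± 1.54 CPM, and Cyr61, a matricellular protein gene, from 21.5 ± 4.35 to 53.5 ± 6.96 CPM. Fos, past the threshold over the list alone, was at 28.5 CPM in control and 59.1 CPM in trained mice, a log2 difference of 1.07 ± 0.25. The list was called higher in astrocytes (adjusted p = 6.22e-06 by camera), which was lost with an estimated correlation (adjusted p = 0.726). Ddit4, an inhibitor of mTORC1 induced by glucocorticoids, rose from 49.1 ± 1.95 to 89.5 ± 10.7 CPM, and Sik1, a salt-inducible kinase gene of the delayed activity list, from 26.0 ± 4.04 to 53.8 ± 11.2 CPM.

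Of the remaining 10 astrocyte genes, 9 are given here and were named after their values were seen. Cebpb, a transcription factor of acute-phase and metabolic responses, had a log2 fold change of 2.05 ± 0.29, and Foxo1, a transcription factor restrained by insulin signalling, 0.83 ± 0.14. The phosphodiesterase genes Pde10a and Pde8a changed by 2.54 ± 0.44 and 1.07 ± 0.19, the histone demethylase gene Kdm5b by 0.94 ± 0.14, and Arrdc3, Usp53, Arhgap31 and Emd between 1.19 and 1.68. Pde10a, also a marker of striatal neurons, stood at 219, 356 and 133 CPM in control mice 1, 3 and 5 and at 2610, 630 and 867 CPM in trained mice 2, 4 and 6. The other striatal markers summed in astrocytes to 69.3, 76.6 and 66.0 CPM in the controls and 47.7, 60.8 and 67.0 CPM in the trained mice, without TMM scaling, and the glutamatergic markers to 107, 121 and 107 CPM against 84.9, 145 and 84.8 CPM.

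Of 12323 astrocyte genes tested, 947 (7.68%) had an unadjusted p under 0.05, and DESeq2 called 57, of which 19 were among the 20. The count fell to 8 without control mouse 1, 0 without control mouse 5, 7 without trained mouse 6, 10 with median UMIs (8 among the 20) and 11 with mitochondrial percent as covariate (6 among the 20, and 1 of the 11 lower), and was 32 without control mouse 3 and 76 without trained mouse 4. All of the 20 stayed higher with either covariate, with a median log2 fold change of 1.38 (median SE 0.226) with median UMIs and 1.30 (0.246) with mitochondrial percent, against 1.34 (0.198) without. With either covariate 8 of the 20 kept at least their own log2 fold change. With mitochondrial percent Nr4a2 went from 3.25 to 1.86 and Nr4a3 from 2.79 to 1.75 (edgeR adjusted p 0.118 and 0.175).

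**Figure D1:**
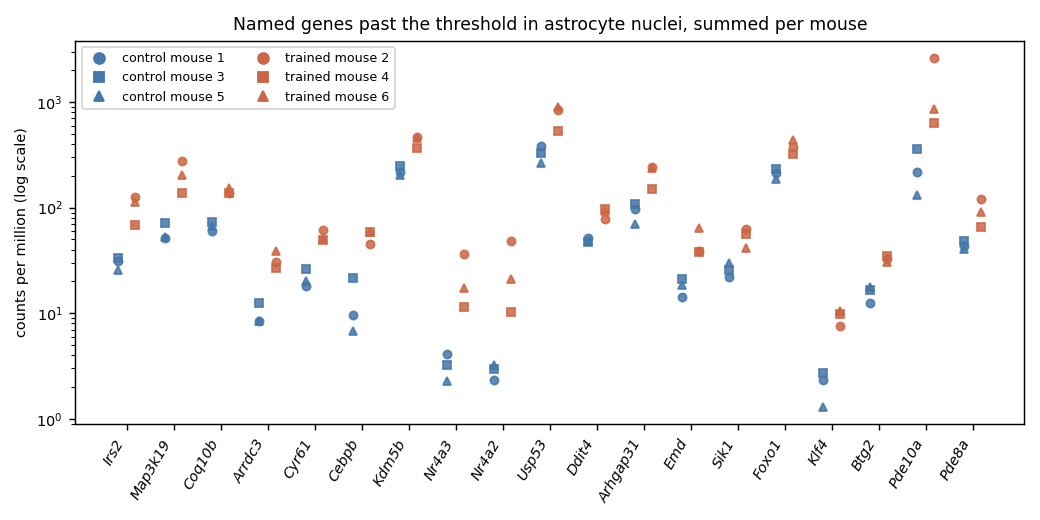
CPM (log axis) of 19 of the 20 genes past the threshold in astrocyte nuclei, 1 point per mouse, with control mice in blue and trained mice in orange. For every gene shown the 3 trained mice lie above the 3 control mice.

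In the other non-neuronal classes (microglia and macrophage, oligodendrocyte, oligodendrocyte precursor, endothelial, pericyte and smooth muscle, vascular and leptomeningeal), none of 43529 gene tests passed by edgeR. Microglia came nearest: Numb, an inhibitor of Notch signalling, was at 1209 ± 155 CPM in control and 626 ± 92.8 CPM in trained mice (SD, n = 3 each), and Pla2g4a, a cytosolic phospholipase that releases arachidonic acid, at 235 ± 45.4 and 109 ± 15.97 CPM, with adjusted p-values of 0.0526 and 0.0584. In oligodendrocyte precursors Sgk1, a glucocorticoid-induced kinase gene, was at 230 ± 21.5 and 387 ± 73.2 CPM (adjusted p 0.207). In vascular and leptomeningeal nuclei Igfbp5, an IGF-binding protein gene, was at 59.4 ± 23.01 and 447 ± 311 CPM (adjusted p 0.247).

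Unadjusted p-values were under 0.05 in 2097 of these tests (4.82%), and DESeq2 called 20 genes, 16 of them vascular and leptomeningeal. The edgeR count was 194 without trained mouse 6, 15 without control mouse 3, 4 without trained mouse 4, 3 without control mouse 1 and 1 without control mouse 5.

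With all nuclei summed (19546 genes), no gene passed by edgeR, 635 (3.25%) had an unadjusted p under 0.05, and DESeq2 called 6. Blnk had the smallest p, at 21.3 ± 0.499 CPM in control and 31.2 ± 0.788 CPM in trained mice (SD, n = 3 each), a log2 difference of 0.55 ± 0.08 with an adjusted p of 1. None of the 25 immediate early genes tested passed over all genes or adjusted over the list alone. Fos was at 27.0 ± 13.1 and 26.4 ± 11.5 CPM and Arc at 82.5 ± 29.0 and 75.4 ± 31.9 CPM.

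The makeup of nuclei did not differ past the threshold in any of 22 classes (smallest adjusted p 0.665 by edgeR on counts of nuclei). L2/3 IT nuclei made up 10.9% ± 1.94 of control and 10.2% ± 1.41 of trained nuclei (SD, n = 3 each), and astrocytes 12.7% ± 1.39 and 12.0% ± 0.993. Oligodendrocyte precursors stood at 2.90% ± 0.545 and 1.97% ± 0.548, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 mice allow. L5 IT nuclei, at 5.22% ± 0.239 and 6.52% ± 1.08, and Pvalb nuclei, at 3.70% ± 0.493 and 4.36% ± 0.0715, had the same exact permutation p, and no class passed by that test after adjustment. The smallest unadjusted p by edgeR, 0.0567 for oligodendrocyte precursors, left 0 classes under 0.05.

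The glucocorticoid response list was called higher in trained mice in 16 of 21 sums by camera, with list medians of 0.08 to 0.71 on the log2 scale. Every call of the list was lost with an estimated correlation (smallest adjusted p = 0.726). Fkbp5, a co-chaperone of the glucocorticoid receptor, was higher in the trained mean in all 20 sums in which it was tested, by 0.29 to 1.27 on the log2 scale. In L2/3 IT nuclei Fkbp5 was at 41.6 ± 12.2 CPM in control and 81.3 ± 15.1 CPM in trained mice (SD, n = 3 each) and in oligodendrocytes at 167 ± 90.9 and 322 ± 84.4 CPM. Zbtb16, a zinc finger transcription factor, was higher in all 21 sums, by 0.03 to 1.29. Over all genes, 1 member call passed, Ddit4 in astrocytes, and 36 member calls over the 21 sums, called or not, passed when adjusted over the list alone, 11 of them Fkbp5 and 7 Zbtb16. Without control mouse 1 or without trained mouse 4 the list was called in 8 sums.

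The mitochondrially encoded genes were called higher in trained mice in 20 of 21 sums, all but Sncg, with list medians of 0.44 to 1.06. All of these calls were lost with an estimated correlation (smallest adjusted p = 0.726). The cytochrome oxidase subunit gene mt-Co3 was higher in all 21 sums, by 0.44 to 1.14 on the log2 scale. In L2/3 IT nuclei mt-Co3 was at 26.6 ± 2.44 CPM in control and 52.5 ± 25.4 CPM in trained mice (SD, n = 3 each) and in astrocytes at 186 ± 28.6 and 298 ± 51.1 CPM. No member passed over all genes, and 61 member calls passed when adjusted over the list alone, 13 of them mt-Co3 and 11 mt-Co1. Trained mouse 2 had the highest mitochondrial share of all mice, and without it the list was called higher in 13 sums. Counts of these genes are uncertain where nuclear copies share their sequence.

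**Figure D2:**
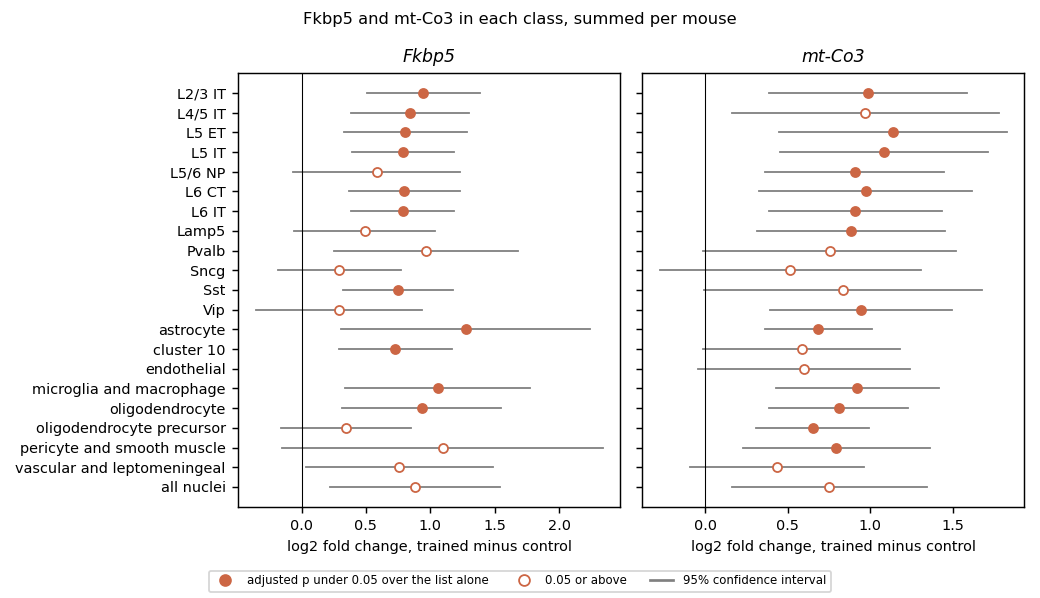
Log2 fold changes (trained minus control, n = 3 mice each) of Fkbp5 and mt-Co3 in each class, with 95% confidence intervals as lines and filled points for an adjusted p under 0.05 over the list alone. Fkbp5 lies above 0 in 20 sums and mt-Co3 in 21.

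Delayed activity-regulated genes, which follow the immediate early genes and include secreted and synaptic effectors, were called higher in L5 IT, cluster 10, all nuclei, astrocyte, Vip and Pvalb sums. All 6 calls were lost with an estimated correlation (adjusted p from 0.726 to 0.917). In L5 IT nuclei 24 of 29 members were higher, and 3 passed when adjusted over the list alone, Tiparp, an ADP-ribosyltransferase gene (43.5 CPM in control, 68.2 CPM in trained mice, log2 fold change 0.65 ± 0.12), Cdkn1a, a cell cycle inhibitor gene (4.04 and 8.62 CPM, 1.10 ± 0.24), and Kdm6b, a histone demethylase gene (25.4 and 37.2 CPM, 0.54 ± 0.16). In cluster 10, 6 of 26 members passed over the list alone, among them Nptx2, Scg2, which encodes a neuropeptide precursor (log2 fold change 0.65 ± 0.16), and Gadd45g (1.35 ± 0.37). Over all genes, Sik1 in astrocytes was the 1 member call that passed. Adjusted p-values of the list were 1.48e-07 in L5 IT and 3.73e-06 in cluster 10 with the preset correlation.

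Immediate early genes were called higher in astrocyte, Sncg, microglia and Vip sums, and the dissection stress list, which shares several of these genes, in oligodendrocyte, Sncg and astrocyte sums. Neither these calls nor those of the other lists held with an estimated correlation (smallest adjusted p = 0.726) or by fry (0.87). Axon guidance and adhesion genes were called lower in 7 sums, all but Sncg non-neuronal, with 3 member calls in these sums adjusted over the list alone, 2 of them the neuronal adhesion genes Cntn5 (259 CPM in control, 44.6 CPM in trained mice) and Efna5 (172 and 51.6 CPM) in pericytes. Voltage-gated channels were called lower in pericyte, vascular and leptomeningeal, and oligodendrocyte sums and higher in L5 ET, and glutamate receptors and scaffolds lower in the same 3 and higher in Lamp5 and L5 ET. Myelin genes were called lower in all nuclei, L6 IT, Sst, L6 CT and L5/6 NP sums. Nuclear-encoded oxidative phosphorylation was called lower in L6 IT, L2/3 IT, Sst and L5 ET, and the clock list in microglia and L6 CT. The presynaptic list was called lower in vascular and leptomeningeal nuclei. Oligodendrocytes made up 13.2% ± 0.724 of control and 11.2% ± 1.74 of trained nuclei (SD, n = 3 each). Calls of myelin genes in neurons and of neuronal lists in non-neuronal classes may come from RNA of other nuclei. This was not tested for these lists, so they do not show a change within the named class. Ribosomal protein genes were called higher in 3 sums (vascular and leptomeningeal, oligodendrocyte, microglia) and lower in Sst, heat shock genes lower in Sst and L5/6 NP and higher in astrocytes, and the actin list higher in L5 ET. Striatal and choroid plexus lists were not called. Across 17 lists, 85 of 330 tests were called, 57 higher and 28 lower. Without control mouse 1 the count was 134.

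Whether the effect of training differed between L2/3 IT and the other projection classes was tested by the interaction with mouse as a block. Mir670hg differed from L5 IT: its level without TMM scaling went from 103 ± 11.1 to 185 ± 27.1 CPM in L5 IT and from 36.8 ± 1.17 to 40.2 ± 10.1 CPM in L2/3 IT (SD, n = 3 each), a difference in log2 fold change of -0.68 ± 0.11 with an edgeR adjusted p of 0.0187. Avil, an actin-bundling protein gene, differed from L6 IT (-4.55 ± 0.59, adjusted p 0.00109) on few UMIs: L6 IT held 6, 4 and 1 UMIs in control mice 1, 3 and 5 and 40, 50 and 1 in trained mice 2, 4 and 6. The clone 4930408O17Rik, named after its values were seen, differed from L5 ET (6.78 ± 1.04, adjusted p 0.0286), where controls held 109 UMIs and trained mice 1, a ratio of 0.0106 with a 95% exact counting interval of 0.000265 to 0.0601. That interval treats the pooled UMIs of each group as independent and holds no spread between mice. In the fit of training in L5 ET alone no gene passed (smallest adjusted p 0.155 by edgeR). The fitted fold of the clone depends on the prior count. Avil and this clone overlap Tsfm and Clmn on the opposite strand, and how strand was counted is not given in the sources used here.

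No gene passed against L6 CT, where 616 of 14785 genes had an unadjusted p under 0.05, against 943, 658 and 548 for L5 IT, L6 IT and L5 ET, and DESeq2 called 2 interactions in all. Of the immediate early genes, 5 differed from L6 IT when adjusted over the list alone, with the training difference more positive in L2/3 IT: Nr4a3 by 0.64 ± 0.16, Nr4a2 by 0.59 ± 0.20, Fosl2 by 0.57 ± 0.17, Dusp1 by 0.54 ± 0.17 and Nr4a1 by 0.28 ± 0.10. Nr4a2 also differed from L6 CT by 0.61. None of them passed over all genes. The total of 3 interactions became 24 without control mouse 3 and 7 without trained mouse 4.

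The share of nuclei high in immediate early genes (3 or more UMIs of the list after thinning to 2000 UMIs) was compared between groups. It counts transcripts and does not by itself show whether more neurons were recently active. In L2/3 IT nuclei it was 18.7% ± 7.47 in control and 16.8% ± 8.87 in trained mice (SD, n = 3 each), a difference of -1.95 points with an exact two-sided permutation p of 0.8. Without thinning the shares were 66.5% and 70.0%, and thinning left out 0 control and 2 trained nuclei of this class. Oligodendrocytes, which served as the background for free RNA, showed 4.89% ± 1.98 and 5.30% ± 2.38 (6.04% and 5.99% without thinning, 2475 control and 1379 trained nuclei left out). Their median depth was 1728.5 UMIs, against 9350 in L2/3 IT. The difference turned to 1.73 points without control mouse 5 and 1.46 points without trained mouse 6.

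In no other class did the share pass after adjustment (Benjamini-Hochberg p of 1 in each of 17). The exact permutation p of 3 against 3 mice cannot fall below 0.1, so no class could have passed whatever its shares. Astrocytes stood at 5.76% ± 1.82 in control and 12.0% ± 3.64 in trained mice (SD, n = 3 each), with an exact permutation p of 0.1, the smallest possible. Microglia and macrophages were at 18.6% ± 5.04 and 26.1% ± 2.93 (exact permutation p 0.2), L6 IT at 21.97% ± 6.81 and 14.6% ± 5.61 (0.2), and L6 CT at 36.2% ± 11.0 and 31.7% ± 13.7 (0.9). Without thinning, astrocytes were at 13.4% and 22.6%, microglia at 15.5% and 24.9%, L6 IT at 75.7% and 73.3%, and L6 CT at 84.5% and 80.3%. Thinning left out 979 control and 508 trained astrocytes and 1299 control and 672 trained microglia, whose median depths were 2773 and 1506 UMIs, and 1 control and 2 trained L6 IT and 7 control and 6 trained L6 CT nuclei, with medians of 10375 and 8126 UMIs.

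**Figure D3:**
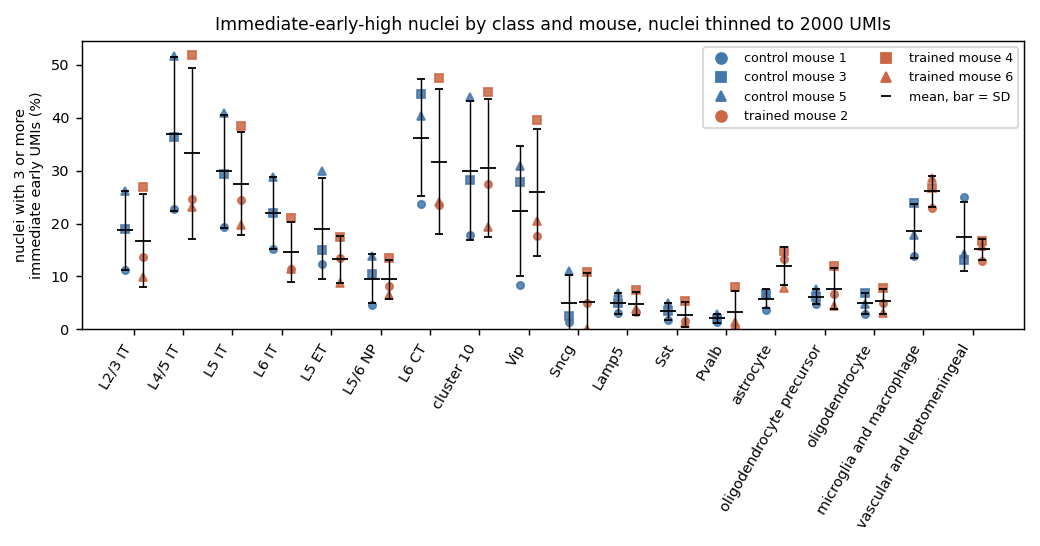
Share of nuclei (%) with 3 or more immediate early UMIs after thinning to 2000 UMIs, by class, 1 point per mouse with the group mean and SD over 3 mice. In L2/3 IT the groups overlap, at 18.7% in control and 16.8% in trained mice.

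Within mice, L2/3 IT nuclei high in immediate early genes (961 nuclei) differed from nuclei without immediate early UMIs (2141 nuclei) in 582 of 7549 genes, 424 higher and 158 lower. Homer1, a postsynaptic scaffold gene with an activity-induced short form, rose from 390 ± 58.8 to 1302 ± 281 CPM (SD, n = 6 mice), a log2 fold change of 1.73 ± 0.06. Tiparp rose from 32.7 ± 7.18 to 270 ± 68.1 CPM (3.07 ± 0.14; 3.065 unrounded), Pcsk1, a prohormone convertase gene, from 20.3 ± 9.50 to 142 ± 51.9 CPM (2.67 ± 0.18), Bdnf, a neurotrophin gene, from 27.9 ± 15.0 to 124 ± 33.0 CPM (2.23 ± 0.17), and its receptor gene Ntrk2 from 547 ± 103 to 1028 ± 206 CPM (0.87 ± 0.06). Tnfaip6, a hyaluronan-binding protein gene, rose from 1.01 ± 1.36 to 83.9 ± 21.2 CPM, the neurofilament gene Ina from 47.1 ± 5.30 to 194 ± 15.2 CPM, and Sik2, R3hdm1 and Pam by 1.22, 0.66 and 0.66 on the log2 scale. All 10 were higher in 6 of 6 mice, and edgeR's adjusted p was 2.61e-190 for Homer1 and at most 7.36e-36 for the others. These p-values match a normal test of the log2 fold change over its SE. They rest on a spread pooled over genes and do not measure each gene's own spread over 6 mice.

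Among the genes lower in the high nuclei, Map2k6, a MAP kinase kinase gene, fell from 115 ± 24.0 to 62.0 ± 18.5 CPM (log2 fold change -0.84 ± 0.15; SD, n = 6 mice), Sphkap, an anchoring protein gene, from 254 ± 32.0 to 177 ± 18.1 CPM (-0.51 ± 0.10), Kcnc2, a fast potassium channel gene, from 652 ± 80.3 to 499 ± 54.1 CPM (-0.36 ± 0.07), and Rbfox1, a splicing regulator gene, from 3868 ± 306 to 3245 ± 319 CPM (-0.26 ± 0.04). Dgkb, Dab1, Cntnap2, Cntnap5a, Robo1 and Ryr2 fell by 0.25 to 0.33 on the log2 scale. The 10 genes were lower in 6 of 6 mice, except Cntnap5a in 5. Their adjusted p-values by edgeR were at most 2.54e-05, and these too rest on a spread pooled over genes.

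Of the delayed activity-regulated list, 20 of 22 tested members rose in the high nuclei (list adjusted p = 1.96e-70 by camera), and with an estimated correlation the adjusted p = 0.00207. Nptx2 rose by 1.68 ± 0.28, Scg2 by 1.59 ± 0.17, Gadd45g by 3.20 ± 0.43 and Nrn1, a neuritin gene, by 0.91 ± 0.11 on the log2 scale (n = 6 mice). Crem and Pmepa1, at 0.70 ± 0.26 (0.695) and 0.19 ± 0.28, did not pass. The axon guidance and adhesion list was called lower (6 of 57 members lower and 1 higher, adjusted p = 0.00615), which was lost with an estimated correlation (adjusted p = 0.0611). Mitochondrially encoded, glucocorticoid response and heat shock lists were called higher (1 of 8, 4 of 7 and 5 of 25 members higher, with 1 glucocorticoid member lower) and the channel list lower (4 of 45 members lower, 1 higher), and these were lost with an estimated correlation (adjusted p = 0.26, 0.191, 0.152 and 0.152). Without the mouse block 313 genes passed, 312 of them among the 582. Without thinning 707 passed, and 285 of the 582 were among them.

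**Figure D4:**
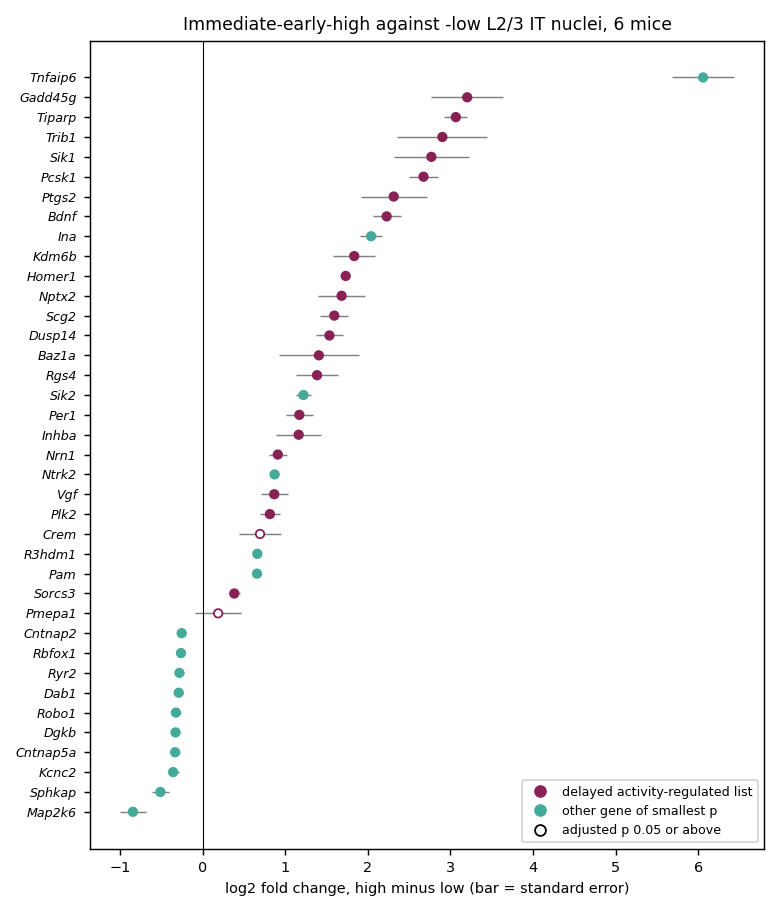
Log2 fold changes (bars are standard errors, n = 6 mice) between immediate-early-high and -low L2/3 IT nuclei for the genes named by the rule, with the delayed activity-regulated list in purple and open points for an adjusted p of 0.05 or above. Among the delayed genes, 20 of 22 lie above 0 with an adjusted p under 0.05.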

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

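The tests with dissection stress in microglia and ribosomal protein genes, the use of thinned sums and of trained mouse 2 left out (both planned as alternatives) to test an explanation, the robust fit, the mitochondrial covariate, the deeper mice as a block and mice 2 and 6 left out were chosen only after the results were seen.

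The difference of training effects between classes was tested for 14379 to 14785 genes per pair of classes, and 3 passed. The log2 fold change of Mir670hg in L2/3 IT minus that in L5 IT was -0.68, that of Avil in L2/3 IT minus L6 IT was -4.55, and that of 4930408O17Rik in L2/3 IT minus L5 ET was 6.78. Adjusted over the immediate early list alone, L2/3 IT minus L6 IT gave 0.64 for Nr4a3, 0.57 for Fosl2, 0.54 for Dusp1, 0.59 for Nr4a2 and 0.28 for Nr4a1, and L2/3 IT minus L6 CT gave 0.61 for Nr4a2. Of 10 splits of the 6 mice, 9 called at least 3 interactions, and another split called 18. The count of 3 is thus not told apart from that of other groupings of the mice.

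Trained mouse 6 had 7.41% of its nuclei in clusters without a name, against at most 0.0544% in each other mouse. Nearly all were in cluster 18, which held 402 nuclei, 389 of them from mouse 6, with a median of 1387 UMIs. Its leading genes included Tmsb10, Timm8b, Fth1 and Ndufa4. These nuclei entered the sums of all nuclei and no class.

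Other splits of the 6 mice into 3 and 3 called many more genes than training in several comparisons, which points to a structure of the samples. The split of mice 1, 2 and 6, the 3 with the highest median UMIs per nucleus, called 345 genes in L2/3 IT (0 by training), 3025 in the other glutamatergic classes (0), 984 in the GABAergic classes (1) and 243 in all nuclei (0). The same mice had the lowest shares of immediate-early-high L2/3 IT nuclei after thinning, 11.2%, 13.6% and 9.96%. Mice 3, 4 and 5 had 18.95%, 26.8% and 26.1%. Depth and this share are therefore not told apart in this split, nor in the depth covariate or the block. In the other non-neuronal classes the split of mice 1, 2 and 3 called 142 (0 by training). With the deeper mice as a block, training called 0 genes in L2/3 IT (925 at an unadjusted p under 0.05), 65 in the other glutamatergic classes, 5 in the GABAergic classes, 18 in astrocytes, 8 in the other non-neuronal classes and 0 in all nuclei (1313 at an unadjusted p under 0.05).

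Where training called 0 genes (L2/3 IT, the other glutamatergic and other non-neuronal classes and all nuclei), all 10 splits call at least as many by construction, so their number tests nothing. In the GABAergic classes 4 of 10 splits called at least 1 gene. Called lists numbered 85 by training and up to 178 in another split, with 8 splits at 85 or more. For the GABAergic classes and the lists, other groupings of the mice thus called as many or more, so these counts are not told apart from theirs. For high against low L2/3 IT nuclei, 1 of 32 swaps within mice, the real one, called 582 genes and the highest other 155. A share of 1 in 32 is the smallest that this test allows, so it does not exclude chance. The groups were formed from immediate early UMIs of the same nuclei, so swaps in some mice cancel genes that vary with them.

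Astrocytes of trained mice had 20 genes higher, and the highest other split called 2 (1 of 10 splits as large, too few for a share under 0.05). Free RNA would raise the genes alike in oligodendrocytes, where the median gain was 0.0158 of that in astrocytes, with ratios of 2.08, 0.507 and 0.511 for Ddit4, Arrdc3 and Arhgap31. Glutamatergic markers in astrocytes stood at 0.938 of the control level. They were at 84.9, 145 and 84.8 CPM in trained mice 2, 4 and 6 and at 107, 121 and 107 CPM in the controls. In sums thinned to 1 total 19 of the 20 genes remained. These values argue against glutamatergic RNA and summed depth as the whole cause. The 6 other stress genes in microglia had a median log2 fold change of 0.067, with a standard error of 0.13 over genes, not mice. Stress genes on the immediate early list were left out of that median. The immediate early list was called higher in microglia at the preset correlation, so dissection stress is not settled. A response of astrocytes to training may remain, and handling during the sessions was not tested apart from it. The count fell to 0 without control mouse 5. Of the 20, 16 passed with the deeper mice as a block, 8 with median UMIs and 6 with mitochondrial percent as covariate. All 20 stayed higher, with medians of the log2 fold change (and of its SE) of 1.35 (0.192), 1.38 (0.226) and 1.30 (0.246) in this order, against 1.34 (0.198) without. In each of these settings 8 of the 20 kept at least their own log2 fold change. With mitochondrial percent the ratio to that value ran from 0.573 to 1.23, and Nr4a2 went from 3.25 to 1.86 and Nr4a3 from 2.79 to 1.75. The lost calls do not by themselves show that depth per nucleus or RNA quality made the difference, and neither is excluded.

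Mitochondrially encoded genes were called higher in 20 sums, and another split (mice 1, 3 and 4) also gave 20 (2 of 10 as large, too few for a share under 0.05). At the preset correlation 13 sums were called without trained mouse 2, so these calls did not rest on that mouse alone. All 9 other splits also gave calls of this list, so calls alone do not mark training. Ribosomal protein genes were called higher in 3 sums, so most sums showed no call of a rise in them. That count was chosen after the results were seen and does not exclude a carryover of cytoplasmic RNA. With an estimated correlation, up to 0.969 between members, no call of the list is left (smallest adjusted p 0.726), so neither test shows that the list differs with training. A difference in the purity of nuclei by mitochondria alone may remain, and a biological difference was not tested apart from it.

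The glucocorticoid response list was called higher in 16 sums, and the split of mice 1, 2 and 5 gave 18 (2 of 10 as large, too few for a share under 0.05). Time of day at collection cannot be told apart from training by the clock genes in all nuclei, since the largest absolute log2 fold change, 0.276 for Nr1d1, has a standard error of 0.25. With an estimated correlation no call of this list is left (smallest adjusted p 0.726). Hormone release during the task could raise the same genes, and it was not measured.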

How the results depend on the processing

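The robust fit, the mitochondrial percent as covariate, the 3 deeper mice as a block and leaving out mice 2 and 6 were chosen only after the data were seen. Of 1967 alternative values of named genes, 1678 kept their direction and side of the threshold, 138 no longer passed, 109 newly passed and 42 reversed. These totals pool genes that passed with genes that did not, so they do not measure how stable the calls were. Of 168 alternative counts and shares, 98 stayed within 1.5 times or the spread, 65 moved and 5 reversed. No paired analysis was possible because control and trained mice share no replicate number. Where no cause is named, the cause was not tested.

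With DESeq2 the counts of genes were 6 in L2/3 IT, 41 in the other glutamatergic classes, 2 in the GABAergic classes, 57 in astrocytes, 20 in the other non-neuronal classes and 6 in all nuclei. Without the filter they were 10 in L2/3 IT, 290, 61, 208 and 352 in the same order of classes, and 82 for the interactions. RLE size factors gave 1 in the other non-neuronal classes, doublets kept gave 0 in the GABAergic and 11 in the other non-neuronal classes, and resolution 0.5, where no cluster took the Sncg name, gave 0 and 2. Sums thinned to 1 total gave 2 in the other glutamatergic and 2 in the other non-neuronal classes.

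With median UMIs as covariate the counts were 76 in the other glutamatergic classes, 24 in the GABAergic classes, 10 in astrocytes and 2 in the other non-neuronal classes. With the mitochondrial percent as covariate they were 4 in the GABAergic classes, 11 in astrocytes and 40 in the other non-neuronal classes, and the robust fit gave 2 in the latter. The deeper mice as a block gave 65, 5 and 8 in the other glutamatergic, GABAergic and other non-neuronal classes. Leaving out both mice 2 and 6 sets trained mouse 4 alone, assumed to vary like the control mice, against the controls, so it tests no stability. The counts were then 1, 6, 0 and 125 (122 in pericyte and smooth muscle) in the other glutamatergic, GABAergic, astrocyte and other non-neuronal classes. Lists called, and sums with the mitochondrially encoded or glucocorticoid list called, were 0 with an estimated correlation and 0 by fry. High against low nuclei gave 313 genes without the mouse block (312 among the 582), 707 without thinning (285), 525 with 2 or more UMIs (439) and 423 without the filter (387).

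Immediate early genes lower in the trained mean of L2/3 IT, none past the threshold, turned higher in some settings. Without mice 2 and 6 the values are those of trained mouse 4 alone against the controls. The deeper mice were also those with the lowest shares of immediate-early-high L2/3 IT nuclei, so the depth covariate and the block are not separate from immediate early levels. The log2 fold change of Egr1 was 0.17 with median UMIs, 0.18 with mitochondrial percent, 0.018 with the deeper mice as a block and 0.32 without mice 2 and 6. In the same order Npas4 gave 0.43, 0.10, 0.18 and 0.54, and Junb 0.62, 0.21, 0.33 and 0.615. Fos gave 0.35 with median UMIs, 0.10 with the block and 0.30 without mice 2 and 6. In all nuclei, with mitochondrial percent, the block and without mice 2 and 6, Arc gave 0.17, 0.18 and 0.445 and Fos 0.25, 0.34 and 0.55.

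The difference in the share of L2/3 IT nuclei high in immediate early genes, -1.95 points, was 0.0181 with 2 or more UMIs, 0.325 with 5 or more and 3.54 without thinning (3.535 unrounded), and -0.758 and -0.437 after thinning to 1000 and 4000 UMIs. With 2 or more UMIs the difference was 0.167 in L5/6 NP, -4.09 in Sncg and -0.748 in cluster 10.

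Leaving out each mouse in turn gave 0 genes in every set for L2/3 IT, all nuclei and class shares. Counts ranged from 0 to 2 in the other glutamatergic, 1 to 13 in the GABAergic, 0 to 76 in the astrocyte and 0 to 194 in the other non-neuronal classes. Called lists ranged from 94 to 134, sums with the mitochondrially encoded list from 13 to 21 and with the glucocorticoid list from 8 to 19, interactions from 2 to 24 and high against low genes from 419 to 524. Log2 fold changes in L2/3 IT ranged from -0.695 to 0.31 for Fos, -0.36 to 0.38 for Arc, -0.67 to 0.29 for Npas4, -0.65 to 0.37 for Junb and -0.25 to 0.24 for Nr4a1. In all nuclei they ranged from -0.52 to 0.115 for Arc and -0.42 to 0.41 for Fos, and for Pmepa1 in high against low nuclei from -0.155 to 0.40. The share difference ranged from -6.97 to 1.73 points. In simulated sums of the other non-neuronal classes 42.6% of doublings were recovered, against 71.9% in L2/3 IT, and whether depth or the spread between mice limits this was not separated.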

Other observations

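The comparison of classes with L2/3 IT, the deeper mice as a block and the list counts among the L5 IT genes were chosen only after the results were seen.

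Within mice, the share of nuclei high in immediate early genes differed between classes. L2/3 IT stood at 17.8% ± 7.41 (SD, n = 6 mice). L4/5 IT, at 35.1% ± 13.9, L6 CT, at 34.0% ± 11.4, cluster 10, at 30.3% ± 11.7, and L5 IT, at 28.7% ± 9.21, were higher in 6 of 6 mice. Each had an exact sign-flip permutation p of 0.03125, the smallest that 6 mice allow, and 0.0443 after adjustment over 17 classes. L5/6 NP, Lamp5, Pvalb, Sncg, Sst, astrocytes, oligodendrocytes and their precursors were lower in 6 of 6 mice. Pvalb, at 2.63% ± 2.73 (2.625), Sst, at 3.06% ± 1.82, and Lamp5, at 4.88% ± 1.87, lay below the oligodendrocyte background of 5.09% ± 1.97, a class with a median depth of 1728.5 UMIs. The median depths of Pvalb, Sst and Lamp5 were 8767, 8045 and 6714 UMIs. Vip was at 24.1% ± 11.0, higher in 5 of 6 mice, with an exact permutation p of 0.0625 (0.0817 adjusted).

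In L5 IT, with the median UMIs per nucleus as a covariate, 76 genes passed by edgeR, 26 higher and 50 lower, and 48 of them also passed with the deeper mice as a block. The deeper mice 1, 2 and 6 also had the lowest shares of immediate-early-high L5 IT nuclei, 19.4%, 24.5% and 19.8%. Mice 3, 4 and 5 had 29.35%, 38.4% and 40.8%, so depth is not told apart from this share in either fit. Epha7, an ephrin receptor gene, fell by 0.92 on the log2 scale (SE 0.10; 0.096), and Tiparp and Nptx2 rose by 0.79 ± 0.10 and 0.88 ± 0.13, against 0.65 and 0.57 without the covariate. Of the delayed activity-regulated list 3 of 29 members were among the higher genes (Fisher's exact test, adjusted p 0.000686), and of the axon guidance and adhesion list 4 of 66 were among the lower genes (0.00153). Of the glucocorticoid response list 2 of 15 were among the higher genes (0.00382). Fisher's exact test treats the genes as independent, and without the covariate the camera calls of the delayed and glucocorticoid lists in L5 IT were lost with an estimated correlation (adjusted p 0.726 and 0.917), and the axon guidance list was not called there (0.889 at the preset correlation). These genes were chosen after their values were seen. The highest other split of the mice with the same covariate called 1 gene, and 1 of 10 splits called as many as training. The splits are too few for a share under 0.05, so these genes are a hypothesis that may belong to training.

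A shared direction of training effects over the 8 glutamatergic classes was tested by limma on their mean per mouse, and 0 of 9977 genes passed (276 at an unadjusted p under 0.05). All 10 splits call at least 0 by construction, so their number tests nothing, and the highest other called 1049, which points to a structure of the samples. Whether the difference of high and low L2/3 IT nuclei itself differs with training was tested by edgeR, and 0 of 7549 genes passed (362 at an unadjusted p under 0.05).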
